A study of Mus musculus with 7 samples.

How the data were processed

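The deposited values were RPKM per gene (reads over exons, scaled by exon length and by the mapped reads of the library) for 7 libraries of polyadenylated RNA from whole thymus of 4 week old C57BL/6 mice. By the submitters' notes, thymus suspensions were passed through a strainer, RNA was taken up in TRI Reagent and cleaned on columns with DNase, reads were aligned with TopHat to mouse build mm9, and bedtools was used. By the series design text, reads over exons were counted in SeqMonk against the NCBI annotation, duplicate transcripts were removed, and genes with a read in at least 1 library were kept. The versions and settings of these programs, the strand of the libraries and the number of reads per library were not given in the sources used here, and the reads themselves were not analysed here.

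The table held 16734 genes, each identified by its symbol. The values were log2 transformed after adding 0.5 RPKM, and the 10498 genes with a mean of at least 1 RPKM over the 7 libraries were tested. Adding 0.5 shrinks the fold change of genes with low values, so their folds are understated. No further scaling was applied. The median log2 shift of a library from the average library lay between -0.146 and 0.136, the lowest in wild type replicate 1 and the highest in wild type replicate 2A. The median change of all tested genes was -0.02 in ZnF1-/- against wild type, -0.05 in ZnF4-/- against wild type and -0.03 in ZnF4-/- against ZnF1-/-.

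Differences were tested with limma 3.58.1 (lmFit, then eBayes with a trend in the prior variance) in R 4.3.3, in 1 fit of the 3 groups with a shared estimate of the spread. Every p of a single gene is a two-sided p from limma, and p values were adjusted by Benjamini and Hochberg over the tested genes of each comparison, with a threshold of 0.05. Errors of log2 fold changes are standard errors (SE) from that fit, with 4 residual and 3.26 prior degrees of freedom, and errors of RPKM are SD over 3 wild type libraries or 2 libraries of a mutant. Mutants with 2 libraries each cannot reach a p under 0.05 in a permutation of labels, where 3 libraries against 2 give 0.1 at the lowest, so no such test was run. The labels do not say that replicates came from separate animals, so a p measures the spread between these samples. Levels of Xist and Ddx3y, given below, differed by sex between replicate 1 of each group and its other replicates, so these were not of 1 animal. Whether wild type 2A and 2B were is unknown. In the fit described here, that spread includes the difference between the sexes.

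Replicate number 1 of each group was read as 76 bp on an older instrument and the replicates numbered 2, 2A and 2B as 50 bp on a newer one, so the number marks a sequencing batch. Deviations from the group mean correlated across genes at 0.489 to 0.737 in the 8 pairs of libraries of different groups that shared a number. A mutant has 2 libraries, whose deviations are mirror images, so pairs with different numbers add nothing. Genes are not independent replicates, so these correlations carry no p. A fit with the replicate number as a block was therefore run beside the unblocked fit, and is called the blocked fit in the text. Its median SE was 0.128 log2 units against 0.203 without the block for a mutant against wild type. Wild type, with replicates 1, 2A and 2B, leans more to the 50 bp batch than a mutant with replicates 1 and 2. Part of any batch or sex difference therefore enters the unblocked fold changes against wild type. Each gene called without the block was also called with it, and moved in the same direction within both batches. For the gene counts and the lists that passed, blocked values stand beside a result where they change its call or move a count by more than 1.5 times.

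Wild type replicates 2A and 2B might have been 1 preparation read again, so their agreement was compared with counting noise. The SD of their log2 ratio, estimated from the median absolute deviation, was 0.259 for genes at 1 to 3 RPKM and 0.143 for genes at 100 RPKM or more. Counting noise alone would then need a depth of 14630000 reads for the first set and 553000 for the second, which a single depth cannot give. For wild type 2A against ZnF1-/- replicate 2, of another genotype, the SD was 0.289 and 0.110 at the same levels. Spread beyond counting noise is also expected between 2 libraries of 1 preparation, so this does not show that they are separate samples. They were kept as 2 libraries of wild type, and averaging them gave 1 call in ZnF1-/- and 127 in ZnF4-/-.

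The fit was tried on simulated libraries with the same design and batch structure, in which 100 genes of ZnF4-/- were changed by 1 log2 unit and 100 by 2 log2 units. Without the block, limma called 34% of the smaller and 91% of the larger changes, with 0 false calls. With the block it called 97% and 100%, with 11 false calls or 5.29% of all calls. In the simulated ZnF1-/- libraries, which held no change, 0 genes were called by either fit. The simulated noise was independent between genes, with the spread estimated by the blocked fit and an additive batch effect, so the setting favours that fit. Shifts of a single library and correlated genes were left out, so these rates may not hold for the real libraries.

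Fixed before the data were examined were 33 gene lists, the rule for naming genes, the test and most alternatives. Of the lists, 29 had at least 3 tested members and were tested with camera, which compares a list with all other genes, at a preset correlation of 0.01, and with fry, which tests whether the genes of a list move one way on balance and, as its mixed test, whether they change in either direction. The list p values were adjusted over the 29 lists of a comparison. At the preset correlation camera called 4, 12 and 13 lists in ZnF1-/- against wild type, ZnF4-/- against wild type and ZnF4-/- against ZnF1-/-. With a correlation estimated from these libraries it called 0 in each, with lowest adjusted p of 0.251, 0.182 and 0.107. With the block and the preset correlation camera called 5, 14 and 13. The directional fry test called 0, 3 and 3 lists without the block, the 3 being the Ikaros family, the innate-like lymphocyte list and mitosis genes each time, and 0, 6 and 8 with it, and its mixed test called 3, 15 and 13.

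Named for each comparison were Ikzf1, the 10 genes with the largest rise and the 10 with the largest fall among genes past the threshold whose libraries did not overlap between groups, and up to 4 members of each list that passed. Where no member of a list passed, the 2 with the smallest p could be given as values, and where fewer than 10 genes passed, the 5 with the smallest p in each direction were given as values. The rule did not name Ikzf2, Notch1, Xist, S100a8, Col1a1 and Sparc, which were taken from the fixed lists after their values were seen. Exceptions and members named from 2 later lists, of B cell and gamma-delta genes, and from a second neutrophil list were likewise singled out by their values. The rule gave 157 genes, not all of which are reported here. Positions are whole gene spans in build mm9, taken from an annotation of that build rather than the one the submitters used. It placed 155 of the named genes, and the exons of 13 of these overlapped exons of another coding gene. Of the genes given values here these were A830010M20Rik, BB031773, Ccr9, Eng and Lyl1. Since the strand of the reads is unknown, reads from a neighbour on either strand cannot be separated there. Auxiliary tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.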

Results

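Gene expression was measured by RNA sequencing in whole thymus from wild type mice and from mice homozygous for a mutation of Ikaros that removes either the first (ZnF1-/-) or the fourth (ZnF4-/-) of its DNA-binding zinc fingers. Ikaros, encoded by Ikzf1, is a transcription factor of the lymphoid lineages and a tumour suppressor of T cells. There were 3 wild type, 2 ZnF1-/- and 2 ZnF4-/- libraries, and the comparisons ask what each finger contributes to the control of genes in the thymus. Between 10185 and 10695 genes per library were listed at 1 RPKM or more. The total reads per library were not given. For the 76 bp libraries, depth was estimated as the one whose whole-read steps, within 0.006 RPKM, best matched the values of genes with few reads. The estimates were 20127000 reads in wild type replicate 1, 14293000 in ZnF1-/- replicate 1 and 6307000 in ZnF4-/- replicate 1. In that order, 30.2%, 39.4% and 54.1% of the low values fell on the steps, where chance gives 9.5%, 10.5% and 10.6%. These depths are best fits and not counts of reads. The depth of the 50 bp libraries is unknown, and no counting interval can be given for them.

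The first principal component held 47.9% of the variance and separated the 76 bp from the 50 bp libraries. The second held 28.9% and placed both ZnF4-/- libraries, at -27.6 and -29.2, apart from the wild type and ZnF1-/- libraries at 7.15 to 18.1. Sex went with the batch and not with the genotype. Xist, the RNA that silences an X chromosome in females, was at 90.6 to 109 RPKM in the 76 bp libraries and at 0.01 to 0.03 RPKM in the others. The Y-linked helicase gene Ddx3y was at 13.2 to 17.4 RPKM in the 50 bp libraries.

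**Figure D1:**
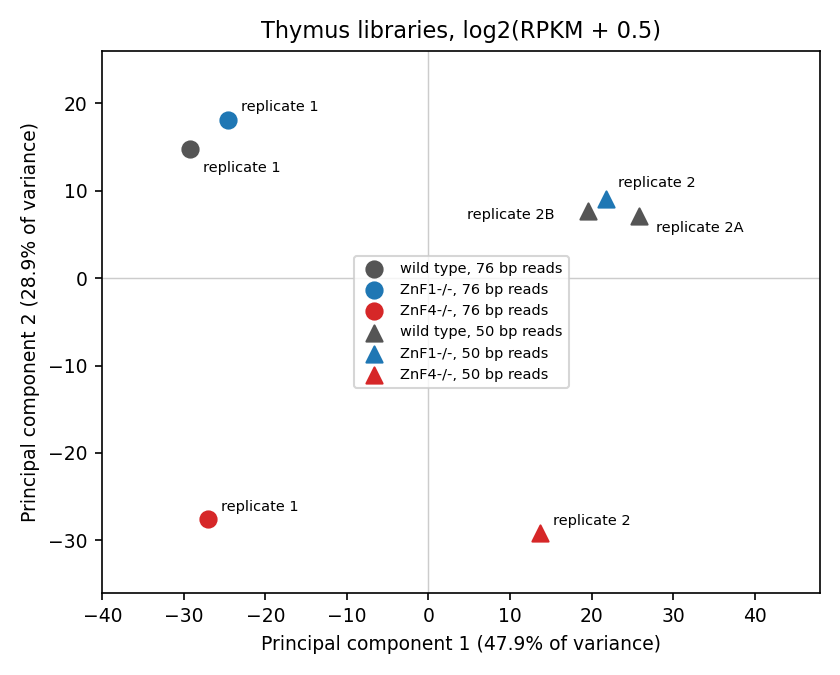
Position of the 7 thymus libraries on the first and second principal components of log2(RPKM + 0.5) over 10498 genes, with circles for 76 bp and triangles for 50 bp reads and colours for the groups. The first axis, with 47.9% of the variance, parts the read lengths, and the second, with 28.9%, puts both ZnF4-/- libraries below -27 and all others above 7.

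Ikzf1 itself (chromosome 11, 11585006 to 11672929, plus strand) was expressed in every library. Its level was 162 ± 18.0 RPKM (SD, n = 3) in wild type, 189 ± 7.98 RPKM (n = 2) in ZnF1-/- and 248 ± 13.4 RPKM (n = 2) in ZnF4-/-. The log2 fold change was 0.22 ± 0.18 in ZnF1-/- (adjusted p = 1.00) and 0.61 ± 0.18 in ZnF4-/- (adjusted p = 0.198), and neither passed. In the blocked fit Ikzf1 rose in ZnF4-/-, by 0.64 log2 units (adjusted p = 0.00737). The level over the whole gene does not show whether the exon of a finger is missing.

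In ZnF1-/- thymus 9 genes changed against wild type, of which 8 rose and 1 fell. The largest rise was that of Fam163b (chromosome 2, 26965900 to 26998011, minus strand), from 2.03 ± 0.18 to 43.5 ± 2.58 RPKM, with a log2 fold change of 4.12 ± 0.14 (adjusted p = 8.46e-05). Crispld2 (chromosome 8, 122516338 to 122576693), which encodes a secreted protein, rose from 0.98 ± 0.217 to 6.95 ± 0.834 RPKM, and the semaphorin gene Sema4g (chromosome 19, 45063591 to 45077887) rose from 2.83 to 14.2 ± 1.22 RPKM. Ctnnd1 (chromosome 2, 84440228 to 84490922), which encodes the cadherin-binding protein p120 catenin, rose from 0.627 ± 0.127 to 4.85 ± 0.0424 RPKM. The single fall was that of Maged1 (X chromosome, 91780813 to 91787482), a member of the MAGE family, from 1.49 ± 0.221 to 0.18 ± 0.0141 RPKM.

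The log2 fold change was 2.34 ± 0.21 for Crispld2 (adjusted p = 0.017), 2.14 ± 0.19 for Sema4g (adjusted p = 0.017), 2.25 ± 0.17 for Ctnnd1 (adjusted p = 0.00869) and -1.55 ± 0.17 for Maged1 (adjusted p = 0.0405). Dkkl1 (chromosome 7, 52462895 to 52467253), related to secreted inhibitors of Wnt signalling, rose by 2.84 ± 0.31 log2 units (adjusted p = 0.0405). Syt14 (chromosome 1, 194723404 to 194861911), of the synaptotagmin family of membrane trafficking proteins, rose from 1.38 ± 0.095 to 7.17 ± 0.375 RPKM or 2.03 ± 0.13 log2 units (adjusted p = 0.00481). Peli2 (chromosome 14, 48740544 to 48880558), which encodes an E3 ubiquitin ligase of innate immune signalling, rose by 1.76 ± 0.17 (adjusted p = 0.0248) and Plekhg3 (chromosome 12, 77634547 to 77680026) by 1.45 ± 0.16 (adjusted p = 0.0405).

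Among the genes with the smallest p that did not pass, Sbf2 was at 6.02 RPKM in ZnF1-/- against 1.67 RPKM in wild type (log2 fold change 1.58, adjusted p = 0.0524), and Cacng4, a subunit gene of calcium channels, was at 15.3 against 0.973 RPKM (3.45 ± 0.48, adjusted p = 0.0917). The others with higher values were Zfp111 (1.72), Myh10 (1.25) and Rnf122, the last at 3.14 against 0.817 RPKM. H19, an imprinted non-coding RNA, was at 1.31 against 8.33 RPKM (-2.27 ± 0.27, adjusted p = 0.0524). Ccdc153 was at 2.13 against 7.75 RPKM and Ccdc88a at 0.17 against 1.75 RPKM, with log2 fold changes of -1.63 and -1.72. Plod2 (-1.21) and the B cell receptor component Cd79a (-1.17) had lower values too. All 10 of these genes passed in the blocked fit, where adjusted p ran from 0.000199 for Cacng4 to 0.0204 for Cd79a.

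The list of gamma-delta, NKT and innate-like lymphocyte genes was lower in ZnF1-/-, with a median log2 fold change of -0.33 over 14 tested members (camera adjusted p = 2.75e-07, adjusted p = 0.251 with an estimated correlation). Of its members 0 passed over all genes by limma, 5 were lower at an unadjusted p under 0.05, 2 fell in the blocked fit and 3 fell when adjusted over the list alone. Sox13, a transcription factor of gamma-delta T cells, was at 1.59 ± 0.276 RPKM against 3.76 ± 0.742 in wild type (adjusted p = 0.272, blocked 0.0242). Blk, a kinase of B cells and some gamma-delta T cells, was at 0.535 ± 0.148 against 1.80 ± 0.286 RPKM (adjusted p = 0.181, blocked 0.0407). B cell markers went with this list in part. Of 5 tested, Cd79a was at 0.425 against 1.59 RPKM, whereas Cd79b was at 30.2 ± 6.82 against 17.1 ± 2.21 RPKM. When adjusted over the list alone and in the blocked fit, 1 B cell marker rose and 2 fell, and the list as a whole did not pass (camera adjusted p = 0.0833; mixed fry adjusted p = 0.000658).

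Markers of early thymic progenitors were higher in ZnF1-/- (median 0.29 over 6 tested members; camera adjusted p = 0.000807, adjusted p = 0.251 with an estimated correlation). The adhesion receptor gene Cd44 was at 8.43 ± 1.44 against 4.97 ± 0.864 RPKM (adjusted p = 0.614, blocked 0.0393) and was the 1 member that rose when adjusted over the list alone, and Lyl1, whose exons overlap another coding gene, was at 1.58 against 0.88 RPKM. Over all genes 0 members passed, 2 were higher at an unadjusted p under 0.05 and 1 rose in the blocked fit. Genes of mature single-positive thymocytes and of thymic egress were lower (median -0.12 over 21 members; camera adjusted p = 0.0124, adjusted p = 0.901 with an estimated correlation). In that list 0 members passed over all genes, 3 were lower and 1 higher at an unadjusted p under 0.05, and 1, Ms4a6b, fell when adjusted over the list alone and in the blocked fit, at 12.3 ± 0.481 against 22.1 ± 2.48 RPKM. The call of this list was lost without wild type replicate 1 (median -0.24, adjusted p = 0.31) and without ZnF1-/- replicate 2 (adjusted p = 0.238). The median was -0.19 without wild type replicate 2B.

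Replication-dependent histone genes, whose messages mostly lack poly(A) tails, were higher in ZnF1-/- by a median of 0.52 over 43 tested members (camera adjusted p = 0.000255, adjusted p = 0.931 with an estimated correlation). Of these 0 passed by limma over all genes or when adjusted over the list alone, 0 at an unadjusted p under 0.05 and 0 in the blocked fit. The list's call was lost in the blocked fit, where its median shrank to 0.17 (camera adjusted p = 0.0501). It was also lost without wild type replicate 2A (median 0.27, camera adjusted p = 0.313). Its median was -0.55 without ZnF1-/- replicate 1, 1.56 without ZnF1-/- replicate 2, 0.92 without wild type replicate 1 and 0.20 without wild type replicate 2B. ZnF1-/- replicate 1 also stood apart in the stress-responsive genes Jun, at 16.1 RPKM against 1.29 to 4.03 RPKM in the other libraries, and Dusp1, at 22.4 RPKM against 7.17 to 10.8 RPKM. Immediate-early and heat-shock genes as a list did not pass (median 0.04 over 13 members, camera adjusted p = 0.246). With replicate 1 as the only ZnF1-/- library the list median was -0.097, while the camera direction stayed upward. Median and test differed in sign there, so it is not settled whether the list as a whole was higher.

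Of the other lists, T cell effector cytokines and receptors (adjusted p = 0.00908) and cytosolic ribosomal protein genes (adjusted p = 0.00789) passed as lower in the blocked camera test alone, against 0.0962 and 0.508 without the block. With an estimated correlation neither passed (blocked adjusted p = 0.653 and 0.868). Without wild type replicate 1 and without the block, ribosomal protein genes passed in the other direction (median 0.0800, camera adjusted p = 0.0141). The Ikaros family, the NuRD chromatin remodelling complex that binds Ikaros, Notch targets, double-positive thymocyte markers and genes of TCR signalling did not pass, with medians from -0.11 to 0.02. The list median and the camera direction differed in sign for p53 targets (-0.05) and cholesterol synthesis genes (-0.03), neither of which passed.

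The blocked fit called 92 genes in ZnF1-/-, of which 60 rose and 32 fell, and 404 genes had an unadjusted p under 0.05. Scaling of the libraries to a common median gave 13 rises and 5 falls, quantile normalization gave 10 and 4, and Fam163b alone of the 9 genes passed under every alternative tried. The count of 9 was 1 without ZnF1-/- replicate 1 or wild type replicate 2B, 2 without ZnF1-/- replicate 2 or wild type replicate 2A, and 5 without either ZnF4-/- library.

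**Figure D2:**
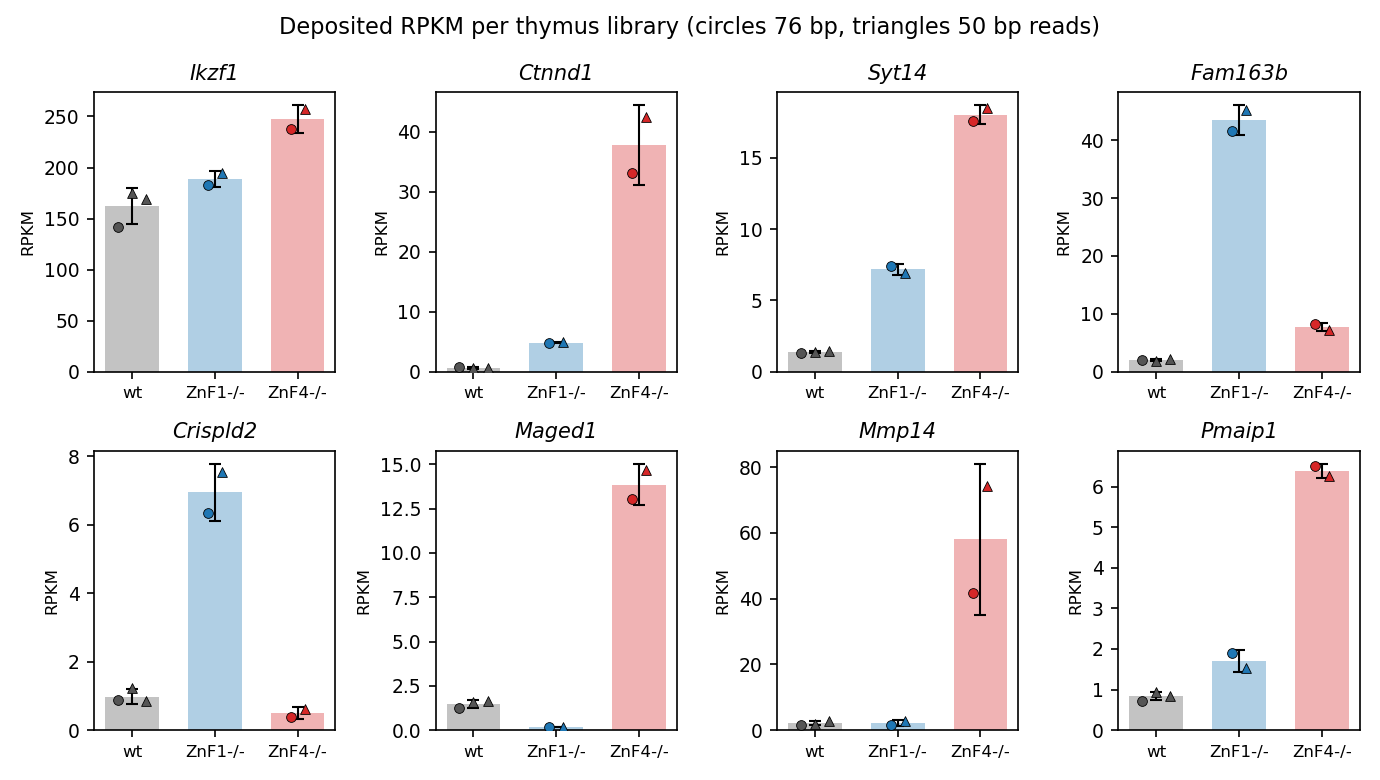
Deposited RPKM of 8 genes in thymus, with bars for the mean, error bars for the SD and a point per library (3 wild type, 2 ZnF1-/-, 2 ZnF4-/-). Fam163b was highest in ZnF1-/- at 43.5 RPKM, Ctnnd1 in ZnF4-/- at 37.8 RPKM, and Maged1 was at 0.18 RPKM in ZnF1-/- and 13.9 RPKM in ZnF4-/-.

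In ZnF4-/- thymus 267 genes changed against wild type, of which 235 or 88.0% rose and 32 fell. Ctnnd1 rose from 0.627 ± 0.127 to 37.8 ± 6.60 RPKM, a log2 fold change of 5.08 ± 0.17 (adjusted p = 7.90e-05). Mmp14 (chromosome 14, 55050441 to 55060095), which encodes a membrane-bound matrix metalloproteinase, rose from 2.06 ± 0.623 to 58.1 ± 23 RPKM (4.49 ± 0.34, adjusted p = 0.00169). Transcripts abundant in fibroblasts stayed low beside it. Col1a1 was at 0.24 RPKM in ZnF4-/- against 0.09 RPKM in wild type, and Sparc at 0.135 against 0.14 RPKM. At levels this near the floor, it cannot be told whether such transcripts changed. Ly6d (chromosome 15, 74592486 to 74593997), a surface protein gene of lymphoid cells, fell from 383 ± 119 to 103 ± 0.728 RPKM (-1.84 ± 0.31, adjusted p = 0.0285). Ikzf3 and Ikzf4, which encode the Ikaros relatives Aiolos and Eos, rose.

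Further large rises were those of F2 (chromosome 2, 91465477 to 91476571), the gene of prothrombin, from 0.22 to 6.44 RPKM (3.27 ± 0.18, adjusted p = 0.000811), and of the keratin gene Krt18 (chromosome 15, 101858647 to 101862457), from 0.637 to 9.96 ± 3.37 RPKM (3.17 ± 0.24, adjusted p = 0.00169). Gria2, a subunit gene of glutamate receptors, rose from 0.07 to 4.55 RPKM and Sertad4 from 0.507 to 7.98 RPKM. Syt14 rose to 18.0 ± 0.651 RPKM (3.30 ± 0.13, adjusted p = 0.000149), and the unnamed transcript Gm4371 rose from 0.773 to 13.9 RPKM. Lmcd1 was listed at 0 RPKM in the wild type libraries and at 5.68 and 3.44 RPKM in ZnF4-/-. Evc (chromosome 5, 37680337 to 37728133), a gene of the primary cilium, had a wild type mean of 0.00333 RPKM and was at 4.25 and 8.01 RPKM in ZnF4-/-. Of the 235 rises, 73 were in genes with a wild type mean under 1 RPKM, 147 in genes at 1 to 10 RPKM and 15 in genes above.

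Besides Ly6d, the largest falls included Tubb2b (chromosome 13, 34218877 to 34222223), a beta-tubulin gene, from 17.5 ± 3.45 to 4.36 RPKM (-1.90 ± 0.29, adjusted p = 0.017), the doublecortin-like kinase gene Dclk2, from 12.1 to 3.10 RPKM (-1.83 ± 0.22, adjusted p = 0.00605), and Fgf13, of the fibroblast growth factor family, from 12.3 to 3.17 RPKM. Chst10 fell by 1.68 log2 units, to 4.04 RPKM, Unc5cl by 1.55 from 13.3 RPKM, and the calcium channel gene Cacna1e from 6.94 to 2.06 RPKM. Mcoln3 (-1.57), 5730422E09Rik (-1.68) and BB031773 (-1.73) completed the 10 largest falls, and the exons of BB031773 overlap another coding gene.

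The Ikaros family was higher in ZnF4-/- as a list (median 0.74 over 5 members; camera adjusted p = 4.75e-05, adjusted p = 0.182 with an estimated correlation). Over all genes 2 members rose, and 4 rose in the blocked fit and when adjusted over the list alone. Ikzf3 (chromosome 11, 98326216 to 98407345) rose from 90.0 ± 6.76 to 157 ± 8.78 RPKM (0.80 ± 0.15, adjusted p = 0.0459) and Ikzf4 (chromosome 10, 128067899 to 128083047) from 2.50 to 6.67 RPKM (1.24 ± 0.18, adjusted p = 0.0167). Ikzf2, the gene of Helios, was at 26.7 against 16.2 RPKM (adjusted p = 0.283, blocked 0.0181). The list shares Ikzf2 with the regulatory T cell markers.

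Innate-like and mature T cell genes were higher. In the list of gamma-delta, NKT and innate-like lymphocyte genes 3 of 14 members rose over all genes, 5 in the blocked fit and 6 when adjusted over the list alone (median 0.42; camera adjusted p = 2.44e-07, adjusted p = 0.182 with an estimated correlation). The NK receptor gene Klrd1 rose from 0.847 to 3.77 RPKM (1.67 ± 0.19, adjusted p = 0.00477), the chemokine receptor gene Cxcr3 from 0.923 to 3.16 RPKM, and Nkg7, of cytotoxic granules, from 14.5 to 28.9 RPKM. Of 21 genes of mature single-positive cells and egress 2 rose, 8 rose and 1 fell in the blocked fit, and 8 rose when adjusted over the list alone (median 0.33; camera adjusted p = 0.0037, adjusted p = 0.463 with an estimated correlation). That median was 0.083 without ZnF4-/- replicate 2 and 0.58 without ZnF4-/- replicate 1. S1pr1, the receptor that guides thymocytes out of the thymus, rose from 11.1 ± 1.25 to 23.6 ± 3.84 RPKM (1.05 ± 0.18, adjusted p = 0.0283) and Slfn1 by 1.04 log2 units from 16.7 RPKM. Regulatory T cell markers were higher too (median 0.53 over 12 members, 0.24 without ZnF4-/- replicate 2; camera adjusted p = 0.000226, adjusted p = 0.463 with an estimated correlation). Of these 0 passed over all genes by limma, 5 were higher at an unadjusted p under 0.05, 6 rose in the blocked fit and 5 rose when adjusted over the list alone. The interleukin 2 receptor gene Il2rb, which the innate-like list holds too, was at 32.6 against 13.1 RPKM (1.29, adjusted p = 0.0692, blocked 0.00029). The receptor gene Il18r1 rose from 1.12 to 4.92 RPKM (1.73, adjusted p = 0.0118) and Il12rb1 fell from 10.1 to 3.53 RPKM (-1.38, adjusted p = 0.0394), both of the T cell effector list, over all genes and over the list alone. That list did not pass (adjusted p = 0.954).

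Interferon-stimulated and MHC class I genes were higher in ZnF4-/-. Of 18 interferon-stimulated genes 3 rose, 9 in the blocked fit and 7 when adjusted over the list alone (median 0.52, 0.29 without ZnF4-/- replicate 2; camera adjusted p = 9.46e-08, adjusted p = 0.399 with an estimated correlation). Oasl2 rose from 3.25 to 11.3 RPKM (1.66 ± 0.23, adjusted p = 0.0116), Xaf1 from 3.80 to 7.92 RPKM and Usp18 from 8.16 to 15.6 RPKM. Of 16 genes of the MHC class I pathway 2 rose, 7 rose and 1 fell in the blocked fit, and 5 rose when adjusted over the list alone (median 0.45; camera adjusted p = 0.000534, adjusted p = 0.399 with an estimated correlation). H2-K1, a classical class I gene, rose from 86.9 ± 10.4 to 163 ± 3.94 RPKM (0.91 ± 0.17, adjusted p = 0.0372), and Nlrc5, the transactivator of class I genes, from 6.65 to 13.2 RPKM. Class I genes resemble one another in sequence, and how reads shared between them were assigned is not known.

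Notch pathway genes and targets were higher as a list (median 0.40 over 13 members; camera adjusted p = 0.0215, adjusted p = 0.701 with an estimated correlation), and the call was lost without wild type replicate 1 (median 0.21, adjusted p = 0.0595) and without ZnF4-/- replicate 1 (adjusted p = 0.14). Only Igf1r (chromosome 7, 75097713 to 75371484) of these rose over all genes, from 6.32 to 20.4 RPKM (1.62 ± 0.20, adjusted p = 0.00627), 1 rose and 1 fell when adjusted over the list alone, and 4 rose and 1 fell in the blocked fit. Notch1 was at 87.8 against 49.1 RPKM (adjusted p = 0.356, blocked 0.00871), a gene chosen after its values were seen. The progenitor marker Kit rose from 2.14 to 4.41 RPKM (0.89 ± 0.15, adjusted p = 0.0267), while its list, with Kit as the 1 rise when adjusted over the list alone, did not pass (adjusted p = 0.442). Of 15 p53 targets and apoptosis genes 2 rose, over all genes and when adjusted over the list alone. These were Pmaip1 (chromosome 18, 66618258 to 66625204), which encodes the apoptosis inducer Noxa, from 0.837 ± 0.101 to 6.39 ± 0.17 RPKM (2.37 ± 0.17, adjusted p = 0.00155), and the cell cycle inhibitor gene Cdkn1a, from 2.88 to 8.29 RPKM (1.41, adjusted p = 0.0217). That list did not pass (adjusted p = 0.829), and its median, -0.12, and mean, 0.08, differed in sign.

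Double-positive thymocyte markers were lower in ZnF4-/- (median -0.33 over 20 members; camera adjusted p = 0.000534, adjusted p = 0.529 with an estimated correlation). Of these 0 passed by limma over all genes or when adjusted over the list alone, 3 were lower at an unadjusted p under 0.05, and 3 fell in the blocked fit. The chemokine receptor gene Ccr9, whose exons overlap another coding gene, was at 190 against 316 RPKM (-0.74, adjusted p = 0.12, blocked 0.011). Mitosis genes were lower as well, by a median of -0.17 over 25 members (camera adjusted p = 0.00672, adjusted p = 0.399 with an estimated correlation), with 0 members past the threshold over all genes, over the list alone, at an unadjusted p under 0.05 or in the blocked fit. Their call was lost without wild type replicate 1 (median -0.23, camera adjusted p = 0.141). DNA replication genes (adjusted p = 0.0341) and oxidative phosphorylation genes (adjusted p = 0.00923) passed as lower in the blocked camera test alone, against 0.141 and 0.0672 without the block. With an estimated correlation neither passed (blocked adjusted p = 0.747 and 0.761).

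Markers of other cell types moved with these groups. Macrophage and monocyte markers were higher (median 0.52 over 11 members; camera adjusted p = 0.00797, adjusted p = 0.521 with an estimated correlation), with the receptor kinase gene Axl as the 1 member that rose, from 2.30 to 5.23 RPKM, over all genes and over the list alone, and 3 in the blocked fit. Their call was lost without wild type replicate 2B (median 0.32, adjusted p = 0.0644) and without ZnF4-/- replicate 2 (median 0.27, adjusted p = 0.0763). Neutrophil markers were higher (median 0.98 over 10 members; camera adjusted p = 0.000534, adjusted p = 0.553 with an estimated correlation), but all 10 were highest in ZnF4-/- replicate 1, and without that library the median was 0.00251 and the adjusted p 0.431, against 1.86 without ZnF4-/- replicate 2. In that list 0 members passed over all genes, 2 were higher at an unadjusted p under 0.05, 1 rose in the blocked fit and 1 when adjusted over the list alone. Erythroid genes were higher (median 0.64 over 6 members; camera adjusted p = 0.0325, adjusted p = 0.529 with an estimated correlation), with Hbb-b1 at 44.1 against 15.4 RPKM (adjusted p = 0.27, blocked 0.00902). Of these 0 passed over all genes, and 2, at an unadjusted p under 0.05, in the blocked fit and over the list alone, were near-identical copies of beta-globin. That call was lost without wild type replicate 2B (adjusted p = 0.0654) and without ZnF4-/- replicate 2 (median -0.10, adjusted p = 0.333). The erythroid median was 1.41 without ZnF4-/- replicate 1. Of 6 tested thymic epithelial markers 2 rose, Krt18 and Cldn4, with 2 rises and 1 fall when adjusted over the list alone, and the list did not pass (adjusted p = 0.0729). Pdgfrb, the single fibroblast marker with enough reads to test, rose from 1.29 to 4.42 RPKM (1.43, adjusted p = 0.0452).

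The blocked fit called 863 genes in ZnF4-/-, of which 640 rose and 223 fell. Scaling to a common median gave 329 rises and 68 falls, and quantile normalization gave 297 and 77. The count of 267 fell to 105 without ZnF4-/- replicate 1, 112 without ZnF4-/- replicate 2, 114 without wild type replicate 2B and 160 without wild type replicate 2A.

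**Figure D3:**
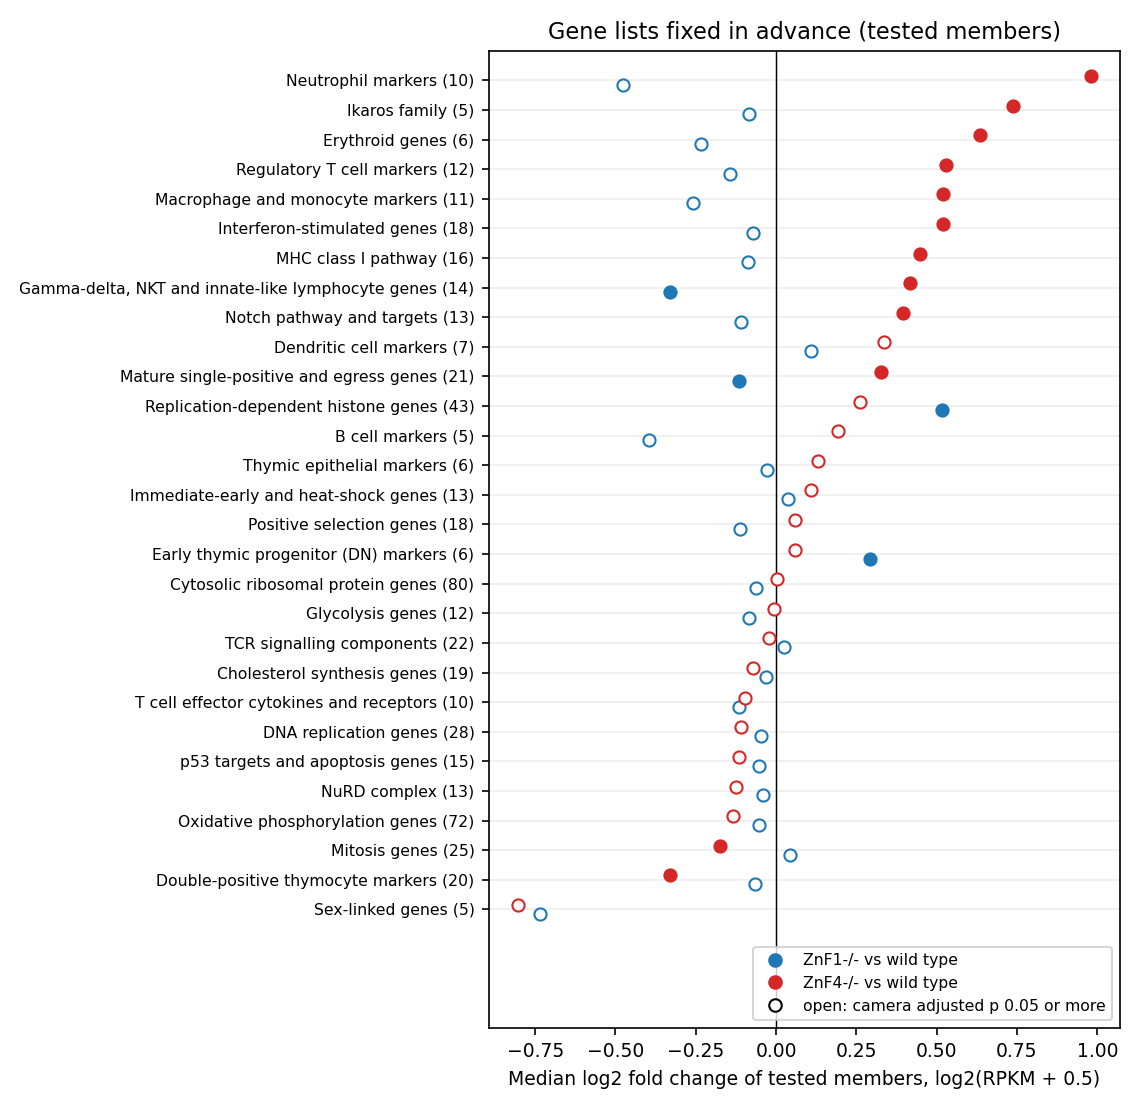
Median log2 fold change of the tested members of 29 gene lists in ZnF1-/- (blue) and ZnF4-/- (red) thymus against wild type, with the number of tested members in brackets and filled points for a camera adjusted p under 0.05 at the preset correlation. With an estimated correlation 0 of the lists passed. The innate-like lymphocyte list was at -0.33 in ZnF1-/- and 0.42 in ZnF4-/-.

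Between the mutants directly, 246 genes differed, of which 212 were higher and 34 lower in ZnF4-/- than in ZnF1-/-. Maged1 was at 13.9 ± 1.17 RPKM in ZnF4-/- and 0.18 RPKM in ZnF1-/-, a log2 difference of 4.40 ± 0.19 (adjusted p = 0.00045). Mmp14 was higher by 4.47 ± 0.37 (adjusted p = 0.00243), Gm4371 by 4.40 ± 0.23 (adjusted p = 0.000839) and Ctnnd1 by 2.83 (adjusted p = 0.0012). The adjacent genes Tmem176b and Tmem176a (chromosome 6, 48783810 to 48791373 and 48791482 to 48795363), which encode membrane proteins of myeloid cells and some T cells, were at 84.0 and 60.1 RPKM in ZnF4-/- against 6.36 and 4.99 RPKM in ZnF1-/- and 12.2 and 8.62 RPKM in wild type. Fam163b, Crispld2, Sema4g and Dkkl1, which had risen in ZnF1-/-, were lower in ZnF4-/- than in ZnF1-/-, by -2.41 ± 0.15, -2.90 ± 0.23, -2.49 and -2.20 log2 units.

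Other large differences were those of Tmem176b (3.63 ± 0.24, adjusted p = 0.0012), Tmem176a (3.44), Ccdc88a (3.44 ± 0.26, adjusted p = 0.002), the steroid-metabolising enzyme gene Akr1c18 (3.37), Dapl1 (3.29 ± 0.49), Ccdc153 (3.28 ± 0.22) and Aldh1l1, of folate metabolism (3.26). Ccdc153 (chromosome 9, 44048760 to 44055389) was at 25.1 RPKM in ZnF4-/-, 2.13 RPKM in ZnF1-/- and 7.75 RPKM in wild type, against which it had risen in ZnF4-/- (1.65, adjusted p = 0.00605). On the lower side were also the laminin gene Lamc1 (-2.08 ± 0.29, adjusted p = 0.0129), Fgf13 (-1.93), Dclk2 (-1.82) and the unnamed transcripts 5730422E09Rik (-2.63), E330020D12Rik (-1.73) and A830010M20Rik (-1.70), the last of which overlaps exons of another coding gene.

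The same 12 lists that passed in ZnF4-/- against wild type also separated the mutants, in the same direction, and positive selection genes passed as a further list. These 2 comparisons share the ZnF4-/- libraries and the estimate of the spread, so their agreement is not independent support. The innate-like lymphocyte list had the smallest p, with 5 of 14 members higher in ZnF4-/- over all genes, 9 in the blocked fit and 11 when adjusted over the list alone (median 0.95; camera adjusted p = 5.02e-14, adjusted p = 0.107 with an estimated correlation). Klrd1 differed by 1.86, Cxcr3 by 1.74, Cxcr6 by 1.47 and Nkg7 by 1.45. Of the mature single-positive and egress genes 3 were higher, S1pr1 (1.44, adjusted p = 0.0112), Slfn1 (1.37) and Ms4a6b (1.35, adjusted p = 0.00815), and over the list alone and in the blocked fit 10 were higher and 2 lower (median 0.58, 0.31 without ZnF4-/- replicate 2; camera adjusted p = 5.89e-05, adjusted p = 0.273 with an estimated correlation). Of the regulatory T cell markers 1 was higher, Tnfrsf4 (1.28), which encodes OX40, 8 in the blocked fit and 6 over the list alone (median 0.73, 0.49 without ZnF4-/- replicate 2; camera adjusted p = 8.1e-06, adjusted p = 0.273 with an estimated correlation).

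The Ikaros family differed through Ikzf4 (1.53) and Ikzf3 (0.89), with 2 members higher over all genes and 3 over the list alone and in the blocked fit (median 0.86; camera adjusted p = 7.39e-05, adjusted p = 0.173 with an estimated correlation). Of the interferon-stimulated genes 1 was higher over all genes, Oasl2 (2.43 ± 0.25, adjusted p = 0.00336), and 7 over the list alone and in the blocked fit (median 0.67, 0.41 without ZnF4-/- replicate 2; camera adjusted p = 4.75e-07, adjusted p = 0.273 with an estimated correlation). Of the MHC class I genes 3 were higher, H2-Q6 (1.41), H2-K1 (1.23) and Nlrc5 (1.02), and 5 over the list alone and in the blocked fit (median 0.34; camera adjusted p = 6.35e-05, adjusted p = 0.273 with an estimated correlation). In the Notch list Igf1r was higher (1.96 ± 0.21, adjusted p = 0.00441) and the feedback inhibitor gene Nrarp lower (-1.39, adjusted p = 0.0406), with 3 higher and 1 lower over the list alone and 5 and 1 in the blocked fit (median 0.36, 0.70 without ZnF1-/- replicate 2; camera adjusted p = 0.0223, adjusted p = 0.668 with an estimated correlation). The Notch call was lost without ZnF1-/- replicate 1 (adjusted p = 0.0627) and without ZnF4-/- replicate 1 (adjusted p = 0.145). Positive selection genes were higher (median 0.18 over 18 members; camera adjusted p = 0.038, adjusted p = 0.709 with an estimated correlation), with the tetraspanin gene Cd53 as the 1 member past the threshold over all genes and over the list alone (0.84, adjusted p = 0.0474) and 2 in the blocked fit. Their call was lost without ZnF1-/- replicate 1 (median 0.022, adjusted p = 0.185) and without ZnF4-/- replicate 2 (median 0.078, adjusted p = 0.283). The median was 0.33 without ZnF4-/- replicate 1 and 0.39 without ZnF1-/- replicate 2.

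Double-positive markers were lower in ZnF4-/- than in ZnF1-/- (median -0.25, -0.37 without ZnF4-/- replicate 2; camera adjusted p = 0.00101, adjusted p = 0.493 with an estimated correlation), with 0 members past the threshold over all genes or the list alone, 4 lower at an unadjusted p under 0.05 and 3 in the blocked fit. Mitosis genes were lower (median -0.22; camera adjusted p = 0.000393, adjusted p = 0.206 with an estimated correlation), with 0 members past the threshold over all genes, the list alone or in the blocked fit and 1 lower at an unadjusted p under 0.05. Their call was lost without ZnF1-/- replicate 1, which leaves a lone ZnF1-/- library, while the median was -0.23. Macrophage markers were higher, with Axl (1.31) past the threshold over all genes and over the list alone and 4 members in the blocked fit (median 0.81, 0.54 without ZnF1-/- replicate 1 and 0.47 without ZnF4-/- replicate 2; camera adjusted p = 0.000211, adjusted p = 0.273 with an estimated correlation). Neutrophil markers were higher (median 1.60; camera adjusted p = 1.06e-05, adjusted p = 0.441 with an estimated correlation), with 0 members past the threshold over all genes, 1 in the blocked fit and 5 over the list alone and at an unadjusted p under 0.05. Without ZnF4-/- replicate 1 the median was 0.64 and the adjusted p 0.321, against a median of 2.42 without ZnF4-/- replicate 2. Erythroid genes were higher (median 1.06; camera adjusted p = 0.00728, adjusted p = 0.441 with an estimated correlation), with 0 members past the threshold over all genes or the list alone and 2 at an unadjusted p under 0.05 and in the blocked fit. That call was lost without ZnF1-/- replicate 1 (median 0.37, adjusted p = 0.0639) and without ZnF4-/- replicate 2 (median 0.32, adjusted p = 0.0866). The median was 1.74 without ZnF4-/- replicate 1 and 1.83 without ZnF1-/- replicate 2. Of 5 B cell markers 2 were higher and 1 lower, over all genes and over the list alone, with Cd79a higher (1.36, adjusted p = 0.0148) and Cd79b lower (-1.36, adjusted p = 0.0189), and the list did not pass (adjusted p = 0.0692).

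The blocked fit called 765 genes between the mutants, of which 545 were higher and 220 lower in ZnF4-/-. After scaling to a common median 299 were higher and 70 lower, and after quantile normalization 261 and 80. The count of 246 was 103 without ZnF1-/- replicate 1, 107 without ZnF4-/- replicate 2, 110 without ZnF4-/- replicate 1, 133 without ZnF1-/- replicate 2 and 153 without wild type replicate 2B.

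Both mutations raised 4 genes, Ctnnd1, Syt14, Fam163b and Peli2, and 0 genes fell in both; the count of 4 was 1 without ZnF1-/- replicate 1 or wild type replicate 2B and 2 without ZnF1-/- replicate 2 or wild type replicate 2A. Independent lists of these sizes would share 0.179 rises, a value that leaves out the shared wild type libraries. Ctnnd1 and Syt14 reached higher levels in ZnF4-/-, and Fam163b was at 7.76 ± 0.679 RPKM there (1.71 ± 0.14, adjusted p = 0.00204) against 43.5 RPKM in ZnF1-/-. Peli2 was at 0.69, 3.53 and 1.71 RPKM in wild type, ZnF1-/- and ZnF4-/-, and its rise in ZnF4-/- was 0.89 ± 0.17 (adjusted p = 0.0458). Maged1 was the 1 gene called in opposite directions. In the blocked fit 35 genes rose and 7 fell in both, and 15 went in opposite directions, 10 of them lower in ZnF1-/- and 5 higher; independent lists, with the same limit, would share 3.66 rises and 0.68 falls.

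Both comparisons used the same wild type libraries, which alone makes their fold changes correlate. Across the 10498 genes, which are not independent replicates, r was 0.208 and rho 0.248, against a mean r of 0.512 in 100 simulations in which neither mutant differed from wild type. The covariance was 0.0214, against 0.0145 ± 0.000517 (SD) in those simulations, and part or all of that excess may come from shared controls. Fold changes taken from opposite batches share no library. They correlated at r = -0.034 (rho -0.141) for ZnF1-/- in the 76 bp batch with ZnF4-/- in the 50 bp batch. The other way round r was 0.0799 (rho 0.049). The covariances were -0.0055 and 0.0093, which differ in sign and lie below 0.0214. The same mutant correlated with itself across batches at 0.398 for ZnF1-/- and 0.552 for ZnF4-/-.

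**Figure D4:**
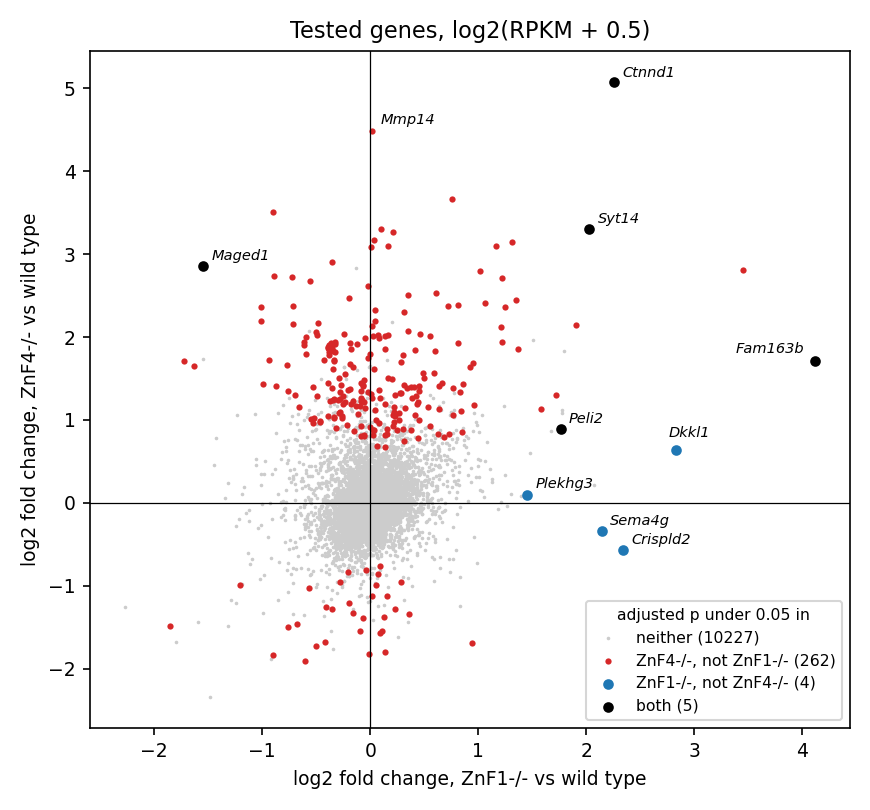
Log2 fold change of 10498 genes in ZnF1-/- (x axis) and ZnF4-/- (y axis) thymus against wild type, coloured by the comparison in which the adjusted p was under 0.05. Ctnnd1, Syt14, Fam163b and Peli2 rose in both, Maged1 fell in ZnF1-/- and rose in ZnF4-/-, and r across genes was 0.208.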

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

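The tests of scaling, of batch or sex and of the ZnF4-/- genotype alone, described in this part, were chosen only after the result was seen.

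Each result in this paragraph was noted because every ZnF1-/- library lay on one side of the wild type libraries and every ZnF4-/- library on the other, and the mutants differed from each other by limma; values are log2 differences of ZnF4-/- against ZnF1-/-. There were 30 such genes among those named, 23 of them lower in ZnF1-/- and higher in ZnF4-/-, and Maged1 (4.40) was the 1 gene called against wild type in both mutants. Higher in ZnF4-/- were Gm4371 (4.40), Tmem176b (3.63), Tmem176a (3.44), Ccdc88a (3.44), Akr1c18 (3.37), Dapl1 (3.29), Ccdc153 (3.28) and Aldh1l1 (3.26). From the lists these were Il18r1 (2.66), Oasl2 (2.43), Ikzf4 (1.53), Cxcr6 (1.47), Nkg7 (1.45), S1pr1 (1.44), H2-Q6 (1.41), Slfn1 (1.37), Cd79a (1.36), Ms4a6b (1.35), Tnfrsf4 (1.28), H2-K1 (1.23), Fosl2 (1.20) and Cd53 (0.84). Lower in ZnF4-/- and higher in ZnF1-/- were Crispld2 (-2.90), 5730422E09Rik (-2.63), Sema4g (-2.49), Lamc1 (-2.08), E330020D12Rik (-1.73), A830010M20Rik (-1.70) and Cd79b (-1.36). Of all 10498 tested genes, 256 or 2.44% had the mutants on opposite sides, against 0.952% by chance if the 7 libraries were exchangeable, which the shared batches make untrue, and 128 of these also passed between the mutants, 114 of them lower in ZnF1-/-.

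More genes rose than fell in ZnF4-/-, 88.0% of those called. Shallow depth of ZnF4-/- replicate 1 is argued against: the 458 genes at least 1 log2 unit higher in that batch had a median of 0.947 in the 50 bp batch, which does not use that library. Scaling is argued against, since 82.9% of the calls were rises after scaling to a common median and 79.4% after quantile normalization, although the falls grew from 32 to 68 and 77. It stays open how far genes at a low level, which can be seen to rise but not to fall, may account for the excess. Of 45 calls at a mean of 10 RPKM or more, 77.8% were rises (95% exact interval 62.9% to 88.8%). In the blocked fit 56.6% were, against 83.7% below 10 RPKM. That mean includes the ZnF4-/- libraries, so a rise can lift a gene past the bound and a fall can take it below. By wild type mean, 15 of the 235 rises were at 10 RPKM or more, against 35 by the mean of all libraries. These shares therefore lean toward rises and cannot decide the question. No biological explanation of the excess was tested.

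B cell and gamma-delta T cell genes had lower values in ZnF1-/-, among them Cd79a, Sox13 and Blk. For the gamma-delta list, sequencing batch or sex is argued against as the whole cause, since its median was -0.338 with the block and -0.330 without (camera adjusted p = 1.54e-06 with the block, 0.653 with an estimated correlation) and -0.522 and -0.343 within the 76 bp and 50 bp batches, while for the B cell list of 5 genes, which passed in neither fit, it stays open, although its median was -0.334 with the block (adjusted p = 0.198) and -0.395 without (-0.179 and -0.611 without ZnF1-/- replicates 1 and 2) and -0.495 and -0.237 within the batches, with 3 genes lower in both. Fewer B cells in the ZnF1-/- suspensions may contribute, as 69.2% of 13 B cell markers, 9 in number, had both ZnF1-/- libraries below all wild type libraries where chance gives 10% for exchangeable libraries; the exceptions were Cd79b, Cd72, Btk and Vpreb1, and whole thymus was not sorted, so this stays open. Fewer gamma-delta T cells of the IL-17 type stays open too. Of 5 further markers of these cells, 40%, Ccr6 and Maf, had both ZnF1-/- libraries below all wild type libraries. By the limit set in advance this share counted against that explanation. All 5 markers had a lower mean in ZnF1-/- than in wild type, however, and 5 markers are too few to decide. A lower expression per cell was not tested and cannot be told apart from fewer cells in these libraries.

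Neutrophil genes were highest in ZnF4-/- replicate 1, with S100a8 at 297 RPKM there against 37.0 to 76.4 RPKM in the other libraries. On a second list of 12 neutrophil genes, written before its values were seen, 11 had a highest value of at least 0.3 RPKM. Of these, 81.8% were highest in that library, where chance gives 14.3% for exchangeable libraries and independent genes. Genes of 1 cell type are not independent. That library also had the lowest estimated depth of the 76 bp libraries, which makes low values more variable, such as BC100530 at 0.36 RPKM. The share of all low genes that were highest there was not determined. Neutrophils or their precursors in that suspension are a candidate source. Retnlg, at 0.03 RPKM, and Padi4 were the exceptions. An effect of the genotype alone is argued against as the whole cause, since over the 10 markers of the first list ZnF4-/- replicate 2 differed from the wild type libraries of its batch by a median of -0.163 (quartiles -0.555 and 0.285) and replicate 1 from that of its own batch by 2.09. In replicate 2, 4 of 10 were above all wild type libraries, where chance gives 25%, so a smaller effect of the genotype, or one that depends on sex or batch, was not excluded.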

How the results depend on the processing

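The alternative that joins the block to a log2 fold change of at least 1, and the fold changes from opposite batches, were chosen after seeing the data. Of the results other than the main counts and Ikzf1, 5695 values stayed on their side of the threshold over the alternatives, 241 newly passed, 419 no longer passed and 9 reversed while called before or after. Of the alternatives for the main counts, 64 stayed within 1.5 times the count, 25 gave more and 30 fewer, and Ikzf1 newly passed in 5 and kept its side in 64. Of the 5695, 85 changed sign while uncalled both times (18 of genes, 67 of lists). Where no cause is named, the cause was not tested. The count in ZnF1-/- was 9, and it was 3 with no filter on low values, 4 at a mean of at least 5 RPKM, 18 after median scaling, 14 after quantile normalization, 92 with the block, 142 with the block and median scaling, 49 with the block and a log2 fold change of at least 1, 1 with wild type 2A and 2B averaged, 27 with both averaged and the block, 5 with only the 2 groups compared, 14 with no trend in the prior variance and 17 at an adjusted p under 0.1. The count in ZnF4-/- was 267, and it was 596 with no filter, 54 at a mean of at least 5 RPKM, 863 with the block, 993 with the block and scaling, 127 with the wild type averaged and 578 with it averaged and the block. At a mean of at least 5 RPKM 7356 genes were tested against 10498, so calls fell by more than the number of tests. Of the 235 rises in the main fit, 200 were in genes with a mean below 10 RPKM. Between the mutants the count of 246 was 576 with no filter, 51 at a mean of at least 5 RPKM, 765 with the block, 889 with the block and scaling and 600 with the wild type averaged and the block. The blocked fit removes the difference between batches from the spread, which lowers the median SE from 0.203 to 0.128. This goes with its larger counts. For a mutant against wild type the block also shifts the fold changes, because the groups differ in their share of each batch. In ZnF4-/- the median of sex-linked genes was -0.80 without the block and -0.03 with it. Histone genes went from 0.52 to 0.17 in ZnF1-/- and from 0.26 to -0.01 in ZnF4-/-. Genes that rose in both mutants numbered 4; genes called in both in the same direction numbered 9 after median scaling, 7 after quantile normalization, 42 with the block, 61 with the block and scaling, 1 with the wild type averaged, 13 with it averaged and the block, 7 with no trend and 9 at an adjusted p under 0.1. With an estimated correlation 0 lists passed in each comparison, against 4, 12 and 13. Ikzf1 in ZnF4-/-, at 0.61, passed after median scaling (0.65, adjusted p = 0.0303), after quantile normalization (0.76, adjusted p = 0.0134), with the block (0.64), with the block and scaling (0.64) and with the wild type averaged and the block (0.66, adjusted p = 0.0292). Leaving out 1 library, which leaves fewer samples and in a mutant a lone one assumed to vary like the others, gave counts of 1 to 10 in ZnF1-/-, 105 to 239 in ZnF4-/- and 103 to 306 between the mutants, 4 to 12, 11 to 14 and 12 to 16 lists, and 1 to 4 genes in both. Ikzf1 then ranged from 0.13 to 0.28 in ZnF1-/-, 0.52 to 0.67 in ZnF4-/- and 0.34 to 0.45 between the mutants, and r between the mutants from 0.0636 to 0.43. Among lists called with or without the library left out, the camera direction reversed for histone genes (medians of -0.55 to 1.56 in ZnF1-/-, -0.76 to 1.38 in ZnF4-/-, -1.30 to 1.00 between the mutants), ribosomal protein genes (-0.18 to 0.0800, -0.21 to 0.32 and -0.24 to 0.30) and neutrophil markers in ZnF4-/-, whose median stayed above 0 (0.00251 to 1.86). Medians changed sign with no turn in the camera direction for erythroid genes in ZnF4-/- (-0.096 to 1.41) and, called only without a library, for immediate-early genes and for ribosomal protein genes in ZnF4-/-. Of the named genes called, 1 of 9 in ZnF1-/-, 15 of 41 in ZnF4-/- and 20 of 47 between the mutants passed under every alternative, and 0 reversed. The blocked fit ended no call of a named gene. Among the 76 bp libraries, the depth of the others being unknown, depth limits low genes most in ZnF4-/- replicate 1, at an estimated 6307000 reads.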

Other observations

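Glycolysis, cholesterol synthesis, oxidative phosphorylation and ribosomal protein genes did not pass in any comparison without the block and with all libraries. In the blocked camera test, against wild type, oxidative phosphorylation genes passed as lower in ZnF4-/- (adjusted p = 0.00923). Ribosomal protein genes did so in ZnF1-/- (blocked camera adjusted p = 0.00789). Among lists that did not pass, leaving out 1 library moved the median by more than 1.5 times in all 25 in ZnF1-/- against wild type, all 17 in ZnF4-/- against wild type and all 16 between the mutants. Many of these medians lie near 0, where a small shift makes a large ratio, so this does not show that they rest on single libraries. In ZnF4-/- against wild type the medians were -0.01 for 12 glycolysis genes (camera adjusted p = 0.954, with a mean of 0.01), -0.07 for 19 cholesterol synthesis genes (adjusted p = 0.198), -0.02 for 22 TCR signalling components (adjusted p = 0.954) and -0.12 for 13 NuRD subunits (adjusted p = 0.149). The methyl-CpG binding NuRD gene Mbd2 had a log2 fold change of -0.67 in ZnF4-/- (adjusted p = 0.18, blocked 0.00582). Ribosomal protein genes had a median of 0.0038 and a mean of -0.01 over 80 members (adjusted p = 0.851), histone genes a median of 0.26 (adjusted p = 0.315), immediate-early and heat-shock genes one of 0.11 (adjusted p = 0.315), dendritic cell markers one of 0.34 over 7 members (adjusted p = 0.12, range 0.069 to 0.52 without 1 library), B cell markers one of 0.19 (adjusted p = 0.829), and positive selection genes one of 0.06 (adjusted p = 0.298). The sex-linked genes, which followed the batch, were at -0.80 (camera adjusted p = 0.851) and at -0.03 in the blocked fit. The list median and the camera direction also differed in sign for the T cell effector list, at -0.10.

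Between the mutants, the immediate-early list (median 0.02, mean -0.07) held 1 gene past the threshold, the AP-1 gene Fosl2 (1.20, adjusted p = 0.0382), and the effector list held Il18r1 (2.66 ± 0.26, higher in ZnF4-/-) and Il12rb1 (-1.51), with list adjusted p values of 0.892 and 0.457. Thymic epithelial markers held Krt18 (3.14) and Cldn4 (2.16), and the p53 list Pmaip1 (1.65), neither list past the threshold (adjusted p = 0.0524 and 0.859). Median, mean and test differed in sign for p53 targets (-0.06, mean 0.08), TCR signalling components (mean -0.05) and sex-linked genes (-0.04, mean 0.01). The remaining lists did not pass, at adjusted p values of 0.21 for progenitor markers, 0.457 for dendritic cell markers, 0.535 for DNA replication genes, 0.212 for NuRD, 0.451 for glycolysis, 0.1 for cholesterol synthesis, 0.828 for ribosomal protein genes, 0.237 for oxidative phosphorylation and 0.177 for histone genes.

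In ZnF1-/- against wild type, the adjusted p values of lists not given with the comparison were 0.173 for positive selection genes, 0.136 for regulatory T cell markers, 0.061 for macrophage markers and for neutrophil markers, 0.371 for dendritic cell markers, 0.75 for thymic epithelial markers, 0.502 for erythroid genes, 0.368 for DNA replication and for glycolysis genes, 0.276 for mitosis genes, 0.958 for interferon-stimulated genes and for p53 targets, 0.69 for cholesterol synthesis, 0.163 for MHC class I genes, 0.809 for sex-linked genes and 0.508 for oxidative phosphorylation. Fibroblast, endothelial and adipocyte markers and the chromosome 11 neighbours of Ikzf1 had 1, 2, 0 and 2 tested members, too few for a list test. Of these, Pdgfrb was at 2.73 RPKM in ZnF1-/- against 1.29 RPKM in wild type, the endothelial gene Eng, whose exons overlap 2 other coding genes, had a log2 fold change of 0.84 in ZnF4-/- (adjusted p = 0.0611, blocked 0.00408), and Fignl1, beside Ikzf1, one of -0.63 in ZnF4-/- (adjusted p = 0.0569, blocked 0.00676).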
